A study of Aedes aegypti with 4 samples.

How the data were processed

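RNA of adult female *Aedes aegypti* was compared on 4 two-colour Agilent arrays, each carrying infected mosquitoes in one channel and uninfected mosquitoes in the other. The infected line was PGYP1, which carries wMelPop, a strain of the bacterium Wolbachia. The uninfected line was PGYP1.tet. Per the labels, adults of 2 and 15 days of age were pooled, the 4 arrays were biological replicates, and 1.5 µg of total RNA was amplified and labelled per sample. Infected RNA was in Cy5 on replicates 1 and 3 and in Cy3 on replicates 2 and 4. The 4 arrays lay on 1 slide and were scanned together.

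The spot signals were unnormalized intensity values of both channels, with the local background median beside each, as written by Agilent Feature Extraction 9.5.3 per the file headers. The same software gave processed intensity values, background-subtracted and dye-normalized within the array per the file headers, and their log10 ratio of red over green. It also gave flags for spots that were outliers, saturated or well above background. The deposited table of processed values held log2 ratios of red over green, 1 per transcript, not turned for the dye swap. This was found by setting each column against the scanner ratios of the same array, with slopes of 0.999 to 1.00 and correlations of 0.997 to 1.00. The medians of its columns were 0.00935, 0.00160, -0.0198 and 0.0198 for replicates 1 to 4, and how it was centred is not stated.

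Each array had 43803 gene probe spots and 1417 control spots. They held 34391 distinct probe sequences for 15351 genes. The values were corrected and tested with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50 on the mean signals. Arrays were normalized by loess, with control spots at weight 0. Outlier-flagged spots were left out. Spots of a probe were averaged, then probes of a gene. A probe entered if it was well above background in the infected channel on all arrays or in the uninfected channel on all arrays. This left 12804 genes, with 2544 not passing the filter and 3 lacking a value on an array. The model had a dye term and an infection term, with 2 residual degrees of freedom and 3.23 prior degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05. All log2 values are infected over uninfected, and fitted values rest on 4 arrays (n = 4) with limma's moderated standard error (SE).

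A step was added to this plan after the data were examined. A bright streak on replicate 2 raised the local background of some spots to 65200, and with those spots in the fit normexp added signal to every spot of that array. The 1st percentile of its corrected signal was then 743.2 in red and 1074 in green, against 54.9 to 57.4 on the other arrays. Spots whose local background exceeded 2 times the array's median in either channel were therefore left out, 37 on replicate 2 and 1 on replicate 1. The percentiles on replicate 2 became 59.5 and 55.1. The number of changed genes with the streak kept was known when this was decided, and the report gives it beside the main count.

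The files do not pair gene identifiers with names. No identifier of the array was in the reference table, and 0 probes had a description other than "Unknown". Of 25 gene lists planned before the data were examined, 20 were defined by words in descriptions alone and had no members to test. The other 5 also had identifiers written down beforehand from general knowledge of the species, 19 in all, and all 19 were on the array. The genes to be named were fixed beforehand as (a) the 10 most raised and 10 most lowered genes with a name or description, of which there were none, (b) the 2 most raised and 2 most lowered without one, by identifier, and (c) from each list up to 3 members past the threshold, or the member with the lowest p. Identifiers are printed for part (b) only.

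Because descriptions were missing, 60 protein motifs were searched in the translated probe sequences, after the files were opened and before any expression value was computed. A family was used if at least 3 genes encoded its motif and at least 4 times as many as in a search of the opposite strand and in one of reversed peptides. This gave 14 families with 220 genes. A family here means genes with that motif in a 60-base probe, so members whose probes lie elsewhere are missed and short motifs can match unrelated peptides.

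Lists and families with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. Enrichment among raised genes was tested with one-sided Fisher's exact tests over all genes tested, and again with genes that share a probe sequence counted once, which was added after the results were seen. A gene not well above background in uninfected females on any array was to be given a lower bound. This was the mean infected level over the floor of the uninfected channel or its own signal there, whichever was higher.

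The alternatives were no background correction, the scanner's processed signals, median centring, Aquantile between arrays, no filter or a stricter filter on dim probes, no dye term, eBayes with trend and robust, the probe as the unit, the deposited value table, and each replicate left out. The fit as first planned, with the streak kept, stands beside them. Settings added after the data were examined had a term for replicates 1 and 2 against 3 and 4, or left out genes with only shared probes. Figures were drawn with matplotlib 3.10.9.

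The fit was tested on simulated data for infected against uninfected with 12804 genes. It called 8% of 50 genes changed 1.5-fold, 72% of 50 changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 16-fold. Beside these, 10 unchanged genes were called, and 0 were called with no gene changed. A simulated list of 12 genes shifted 4-fold was called by camera and by fry, and an unshifted one by neither. Simulated genes varied independently of each other, while the estimated correlation of the antimicrobial peptide list was 0.488. The simulation therefore says nothing of set calls on correlated genes, nor of false calls where genes vary together. It also held more changed genes than the 65 called on the real arrays, which eases the adjusted threshold. The shares called may therefore be too high for these data. The number of arrays limits the precision, so changes under 2-fold were mostly out of reach.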

Results

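Gene expression was measured in adult females of *Aedes aegypti* line PGYP1, infected with the Wolbachia strain wMelPop, against females of the uninfected line PGYP1.tet. The comparison asked which genes of the mosquito differed in expression between infected and uninfected females. There were 4 biological replicates, each a pool of mosquitoes of 2 and 15 days of age, and each array held 1 infected and 1 uninfected sample. Spots well above background made up 82.1% to 85.5% of gene probe spots in the infected channel and 80.5% to 86.4% in the uninfected channel.

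Of 12 genes listed as antimicrobial peptides, immune effectors that act against bacteria, 7 were higher in infected females past the threshold, 0 were lower and 5 did not pass. The list was written from general knowledge, and the probes of 5 members encode a cecropin motif and those of 3 a defensin motif, while the identity of the others has no support in the files. The median member was 19.1-fold higher (log2 4.25), and camera placed the list above other genes (p = 5.36e-17), a call lost with a correlation estimated from the data (p = 0.0726). AAEL000611, the most raised gene of all, was 53.1-fold higher (log2 5.73 ± 0.40 SE, n = 4; limma adjusted p = 0.0177). AAEL000625, which rests on 1 probe past the filter, was 33.3-fold higher (log2 5.06 ± 0.40 SE, n = 4; limma adjusted p = 0.0230). Without the filter on dim probes its log2 ratio was 4.42 ± 0.70 SE (limma adjusted p = 0.257). Probes of both encode the motif of cecropins, small peptides that disrupt bacterial membranes.

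Another list member with the cecropin motif was 28.3-fold higher (log2 4.82 ± 0.23 SE; limma adjusted p = 0.00745). The lowest adjusted p on the list, 0.00542 from limma, belonged to a pair of genes with the motif of defensins, another class of antibacterial peptide. They had log2 ratios of 4.22 ± 0.18 SE and 4.21 ± 0.18 SE. All probes of this pair are shared with another gene, so the pair cannot be separated and amounts to 1 measurement. Adjusted over the list alone, 9 members rose and 0 fell. All 12 members had a positive log2 ratio, from 0.18 to 5.73, and 8 of them had a positive ratio on every array.

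Of the 5 list members that did not pass, 4 had log2 ratios of 0.18, 0.19, 0.54 and 0.67, each with 1 array of the opposite sign. The other had a log2 ratio of 5.08 (limma adjusted p = 0.0588), with values of 6.46, 6.10, 5.69 and 2.08 on replicates 1 to 4. The estimated correlation between genes of the list was 0.488. The limma test fry gave an adjusted p of 0.0104, over the 1 list tested. Without replicate 1 or without replicate 3, 4 of the 7 raised members passed, and AAEL000625 did not (limma adjusted p = 0.0584 and 0.0981). Without replicate 2, 6 passed, and AAEL000611 did not (limma adjusted p = 0.0505). Without replicate 4 all 7 passed. With 1 replicate left out, the log2 ratio of AAEL000625 ranged from 4.45 to 5.67 and that of AAEL000611 from 5.19 to 6.27. Without the filter on dim probes 0 of the 7 passed, although the list median stayed at 4.25 and AAEL000611 at 5.73 (limma adjusted p = 0.113).

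Genes were also grouped by motifs encoded in their probes, a search set after the files were opened. Of 6 genes with the cecropin motif, 4 rose, more than a random draw would give among the 59 raised of 12804 genes (Fisher's exact test, one-sided, adjusted p = 8.48e-08), and the median member was 32.5-fold higher. Of these 6 genes, 5 are on the antimicrobial peptide list. Adjusted over the family alone, 6 were higher and 0 were lower, and all 6 had a positive ratio on every array. Camera placed the family above other genes (adjusted p = 2.88e-12), but the adjusted p was 0.592 with an estimated correlation. Fry, which tests whether the genes of a set move one way and makes no comparison with other genes, gave an adjusted p of 0.129. Of 3 genes with the defensin motif, all on the list, 2 rose, the pair with shared probes (Fisher's exact test, one-sided, adjusted p = 0.000437). With genes that share a probe sequence counted once, 1 of 2 rose and the call was lost (adjusted p = 0.0661), while the cecropin motif kept 4 of 6 (adjusted p = 9.40e-08). This count joins only genes with an identical probe. Fisher's exact test takes the genes as independent, while the estimated correlation of the cecropin family was 0.681, so its p-values are too small for correlated genes.

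**Figure D1:**
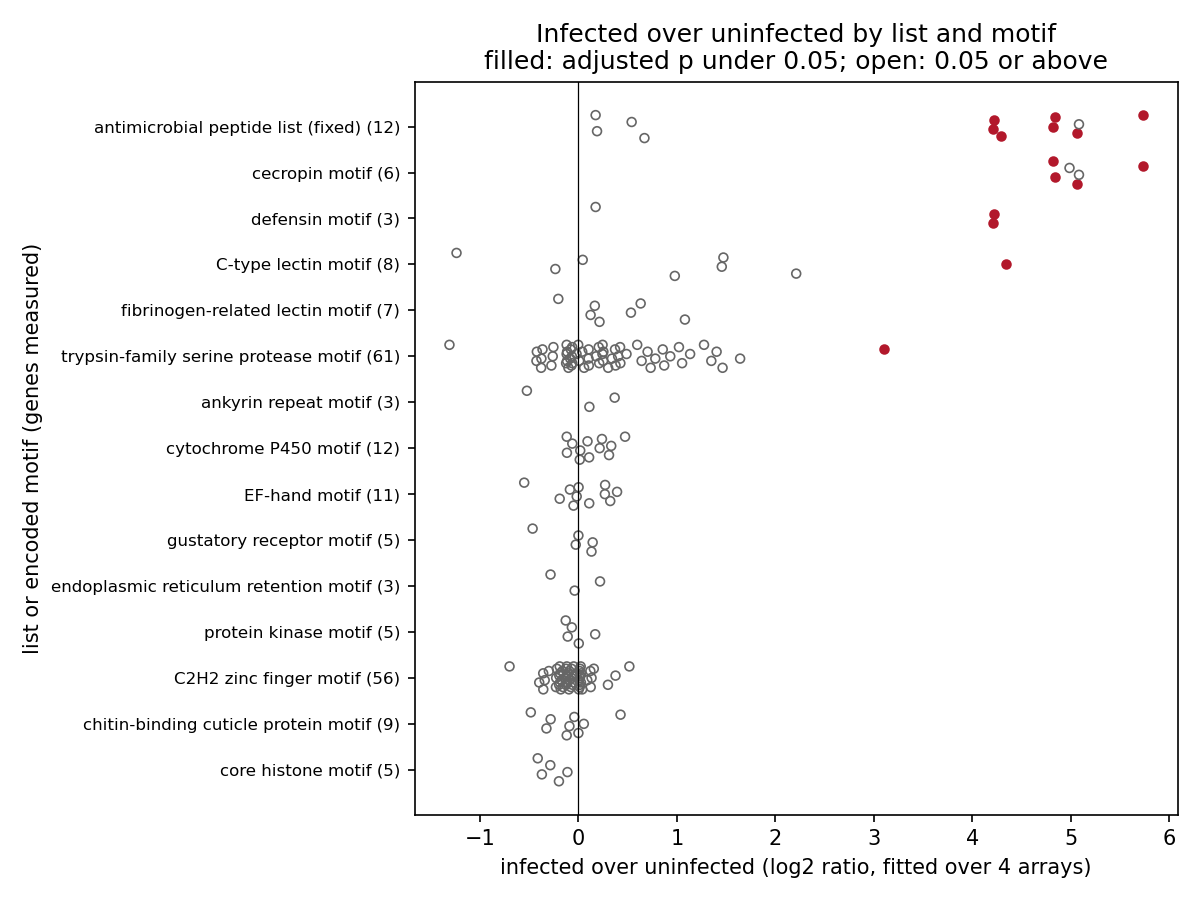
Each point is 1 gene, placed by its log2 ratio of infected over uninfected on the horizontal axis, in rows for the antimicrobial peptide list and 14 encoded motifs. Filled points are past the adjusted p of 0.05. The antimicrobial peptide row holds 7 filled points, with log2 ratios from 4.21 to 5.73.

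In the next 2 families 1 gene each rose, and an excess over a random draw did not pass the threshold (Fisher's exact test, one-sided, adjusted p = 0.169 for C-type lectins and 0.861 for trypsin-family proteases). The unadjusted p of the same test was 0.0363 for C-type lectins and 0.246 for trypsin-family proteases. Of 8 measured genes with the motif of C-type lectins, proteins that bind sugars on microbial surfaces, 1 rose, by 20.3-fold (log2 4.35 ± 0.23 SE, n = 4; limma adjusted p = 0.00745). The family's median log2 ratio was 1.22, and camera gave an adjusted p of 0.0119 (adjusted p = 0.592 with an estimated correlation, 0.290 from fry). Adjusted over that family alone, 5 genes were higher and 1 was lower, the latter at a log2 ratio of -1.24 with the same sign on all 4 arrays (limma adjusted p = 0.0501 over all genes). Of the 5 higher genes, 2 have probes that encode the same peptide and had log2 ratios of 1.46 and 1.47. These 2 may amount to 1 measurement. Of 61 genes with the motif of trypsin-family serine proteases, a class that includes digestive enzymes and proteases of immune cascades, 1 rose. It was 8.60-fold higher (log2 3.10 ± 0.21 SE, n = 4; limma adjusted p = 0.0173). The family's median log2 ratio was 0.21, with a camera adjusted p of 0.00146 (adjusted p = 0.592 with an estimated correlation, 0.290 from fry). Adjusted over that family alone, 10 genes were higher and 1 was lower.

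The other families had no member past the threshold. The 7 genes that matched a short motif of fibrinogen-related lectins had a median log2 ratio of 0.21 (camera adjusted p = 0.0119; adjusted p = 0.592 with an estimated correlation). Some of these matches lie beside stop codons or in peptides of another kind, so the name is not supported for the group. The 5 core histone genes had a median of -0.28 (camera adjusted p = 0.0125, downward; adjusted p = 0.592 with an estimated correlation). The 56 C2H2 zinc finger genes had a median of -0.08 (camera adjusted p = 0.0231, downward; adjusted p = 0.682 with an estimated correlation), and this call was lost under 3 of the 5 other corrections and scalings that alter ratios. Camera did not pass the threshold for the 12 cytochrome P450, 9 chitin-binding cuticle, 11 EF-hand, 5 gustatory receptor and 5 protein kinase genes, with adjusted p from 0.0989 to 0.833. Of the 11 families tested, camera thus called 6. Without replicate 3 it called 2, against 5 to 6 without any 1 other replicate. The ankyrin repeat and endoplasmic reticulum retention families had 3 measured genes each, too few for the set test.

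The other lists fixed beforehand held few genes, and 0 passed over all genes tested. Among 3 genes of Toll, IMD and JAK-STAT signalling, the pathways that control immune effectors, the member with the lowest p had a log2 ratio of 1.05 ± 0.13 SE (limma adjusted p = 0.0592). Adjusted over that list alone, 1 was higher. Of 2 genes of the small RNA pathway, which cuts viral and other RNA, the member with the lowest p had a log2 ratio of 0.64 ± 0.12 SE (limma adjusted p = 0.145). Adjusted over that list alone, 1 was higher and 1 was lower. The 1 gene of immune recognition had a log2 ratio of 0.15 ± 0.16 SE (limma adjusted p = 0.732). The 1 gene of yolk and eggshell on the array was not measured.

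Over all genes, 65 of 12804 changed, 59 raised and 6 lowered, and each had the same sign on all 4 arrays. Raised genes had log2 ratios from 0.82 to 5.73 with a median of 1.73, and 14 were at least 8-fold higher. A change of at least 2-fold was seen in 55 raised and 6 lowered genes. In all, 8 raised and 0 lowered genes encoded one of the 14 motifs, so the identity of most changed genes is not known from the files. The lowered genes had log2 ratios from -1.91 to -1.27 with a median of -1.66. AAEL004342 was lowest, at -1.91 ± 0.16 SE (3.75-fold lower, n = 4; limma adjusted p = 0.0238), followed by AAEL005199 at -1.89 ± 0.18 SE (3.70-fold lower, n = 4; limma adjusted p = 0.0284). AAEL005199 did not pass with the bright streak kept as planned (limma adjusted p = 0.152), nor without replicate 1, 2 or 4 (0.0530, 0.0813 and 0.0792), and AAEL004342 did not pass without replicate 2 or 4 (0.0824 and 0.0588). Of the raised genes, 56 were well above background in uninfected females on every array and 1 on none. That gene was 4.33-fold higher in the fit, with log2 ratios of 1.62, 2.51, 2.41 and 1.92 on replicates 1 to 4. Its own uninfected signal lay above the floor, so the bound set for it equals the fitted fold and is no lower limit.

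The scanner's processed signals gave 124 raised and 35 lowered genes, so 78.0% of changed genes were raised against 90.8% in the counts above. With the bright streak on replicate 2 kept in the background fit, as planned before the data were examined, 41 genes changed, 39 raised and 2 lowered. Without the filter on dim probes 0 changed in limma, with 1659 at an unadjusted p under 0.05, while the log2 ratio of AAEL004342 stayed at -1.91 (limma adjusted p = 0.123). A term for replicates 1 and 2 against 3 and 4, added after the data were examined, gave 275 changed genes, 225 raised and 50 lowered. The counts were 35, 20, 21 and 62 without replicates 1, 2, 3 and 4.

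**Figure D2:**
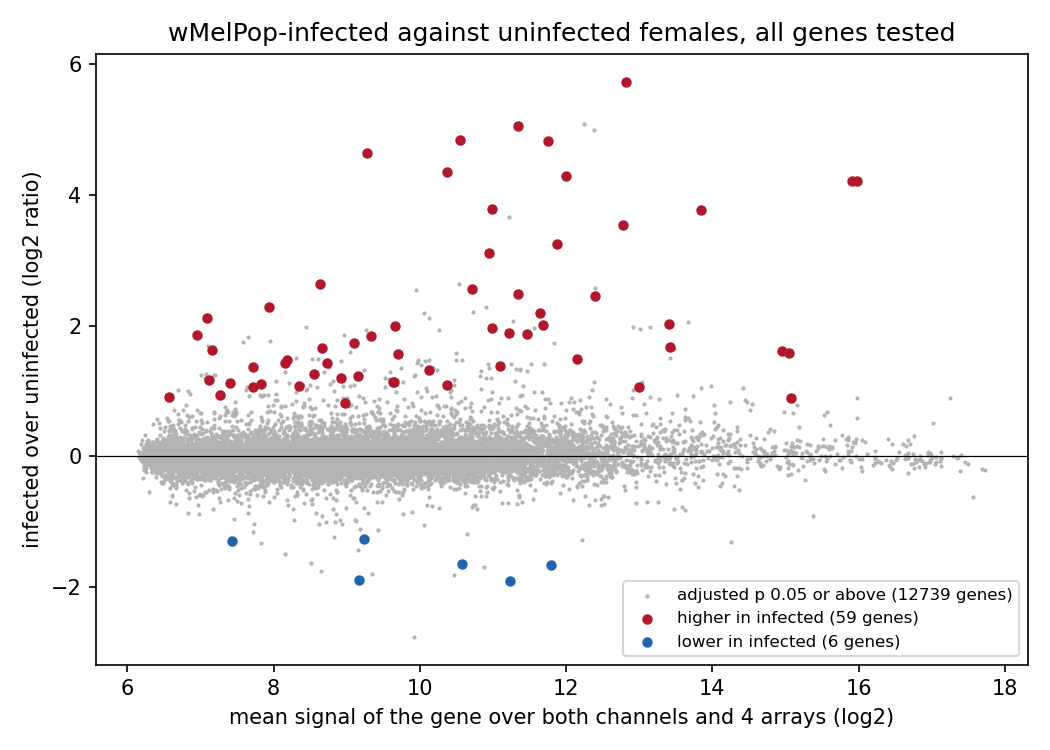
Each point is 1 of 12804 genes, with its mean log2 signal over both channels and 4 arrays on the horizontal axis and its log2 ratio of infected over uninfected on the vertical axis. The 59 raised genes lie between 0.82 and 5.73 and the 6 lowered genes between -1.91 and -1.27.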

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

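The test of shared probe sequence was set before its result was seen. The other tests here, and the pattern of replicate 4, were chosen after the results were in view.

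In replicate 4 the median log2 ratio of the antimicrobial peptide list was 2.96, against 4.62, 4.42 and 4.44 on replicates 1 to 3, a gap of 0.876 of the whole range. The 7 raised members had a median uninfected level of 10.5 (log2) in replicate 4, against 8.58 to 9.71 on the other arrays. Dye orientation as the whole cause is argued against by replicate 2, which had the same dyes and a list median 1.46 above that of replicate 4, against a range of 0.207 over replicates 1 to 3, though replicate 2 had the lowest of those 3 medians and a part of dye stays open. The infected level of the 7 members in replicate 4 was 14.59, within the 14.16 to 15 of the others. The uninfected level of the other 52 raised genes was 8.75, within 8.28 to 9.16. That of the 6 lowered genes was 11.21, above the 10.9 to 10.97 of the other arrays. All these levels were read after loess and Aquantile, which even out differences between whole channels and arrays. They therefore cannot decide on a weak infected channel or a rise of the whole uninfected channel. No biological explanation was tested.

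The rise of antimicrobial peptide genes was set against 4 other explanations. Dye bias as the whole cause is argued against by median log2 ratios of the whole list of 4.82 with infected RNA in Cy5 and 3.85 with it in Cy3, and the within-array normalization by a lowest list median of 4.15 over the other corrections and scalings. The 7 raised members fell into 6 groups with no 15-base stretch in common. This cannot decide on signal of 1 transcript on many probes, since members with cecropin and defensin motifs were unlikely to form 1 group. Signal shared among the similar cecropin motif genes was not measured by such stretches and stays open. A difference between the lines other than infection cannot be told apart from infection, since the number of lines per infection state was 1. A response to wMelPop therefore stays a hypothesis.

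Changed genes tended to have identifiers close in number. Of 65 changed genes, 27 had another within 20, against a median of 10 in 10000 random sets of tested genes (permutation p = 3e-04). With 1 gene kept per group joined by a shared 15-base probe stretch, 26 of 61 did, against a median of 8 (permutation p = 1e-04, the smallest these sets can give). This argues against such shared stretches as the whole cause. Genes with similar probes but no such stretch, as among the cecropin motif genes, were not joined, so signal shared among them stays open. Gene duplicates lying side by side may be a candidate explanation. Positions in the genome were not in the files, so this was not tested.

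Chance flags about 1 group in 20 by this measure, and 5 of 31 were flagged here. The gustatory receptor motif gene with the lowest p had a log2 ratio of -1.67 on replicate 3 against -0.09 to -0.01 on the others (0.953 of the range). The small RNA gene with the lowest p had 0.25 on replicate 2 against 0.74 to 0.79 (0.910 of the range). The SD of log2 ratios over genes was 0.514 on replicate 3 against 0.385 to 0.390 (0.954 of the range). Replicate 2 had 37 spots of the bright streak against 0 to 1 (0.973 of the range).

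Among the 7 ways to assign signs to the 4 arrays that the dye term allows, the real one gave 65 changed genes and the highest other gave 0, and 1 assignment reached 65. These are too few for a share under 0.05.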

How the results depend on the processing

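Leaving out the streak was chosen after seeing the data, so the streak-kept fit is the one first planned. The pair-term and shared-probe settings were chosen after seeing the data, and motif families after the files were opened. The cause of the differences was not tested except where stated. Main counts were 65 changed, 59 raised, 6 lowered and 61 changed at least 2-fold. The same 4 counts were 159, 124, 35 and 152 with the scanner's processed signals, 131, 120, 11 and 102 with no dye term, and 121, 108, 13 and 103 with trend and robust. They were 112, 102, 10 and 99 with the probe as the unit, where a gene counted if any of its probes passed. With the deposited value table they were 127, 109, 18 and 124. Median centring gave 10 lowered genes. Without the filter on dim probes all 4 were 0, with 15351 genes tested and prior degrees of freedom of 1.96 against 3.23. With the streak kept as planned 41 changed, 39 raised and 2 lowered. A term for replicates 1 and 2 against 3 and 4 gave 275, 225, 50 and 156. Of the 65 genes, 61 to 65 were among those called in every planned setting with 4 replicates except no filter (0), 32 with the streak kept and 65 with the pair term. Leaving out 1 replicate gave 20 to 62 changed, 16 to 61 raised, 0 to 5 lowered and 20 to 62 changed at least 2-fold. Without replicates 1, 2, 3 and 4, 23, 18, 18 and 36 of the 65 remained.

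The antimicrobial peptide list was shifted (1 list) in each setting where it was tested except with an estimated correlation, which gave 0. It was not tested with the probe as the unit or without the shared-probe genes. Motif families shifted numbered 6, 0 with an estimated correlation, 0 with fry and 2 to 6 with 1 replicate left out, lowest without replicate 3. The 9 genes named as past the threshold kept it in 81 of 90 other planned fits with all replicates, and the 9 lost were all without the filter, where the log2 ratios of 8 were the same and that of AAEL000625 was 4.42. Aquantile leaves ratios as they are, so its 9 fits could not differ. With the probe as the unit, the probe with the lowest p stood for each gene, which favours passing. With the streak kept as planned AAEL005199 lost it (limma adjusted p = 0.152). They kept it in 28 of 36 fits with 1 replicate left out, and none turned sign. The 8 lost were 3 of AAEL005199, 2 of AAEL004342, 2 of AAEL000625 and 1 of AAEL000611. The signalling gene passed in 5 planned settings, among them the probe as the unit. The immune recognition gene ranged from -0.04 to 0.33 with 1 replicate left out, and was below 0 without replicate 3 (-0.0394). Infected and uninfected samples share each array, so the ratios are already paired within arrays, and no further block was fitted in the main fit. This pairing does not remove structure between arrays, for which only the term for replicates 1 and 2 against 3 and 4 was tried. A slide or scan block was not run, as there was 1 slide and 1 scan. Signal over background kept 2544 genes out of the main fit.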

Other observations

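The replicates were not equally alike. Across genes, which are not independent replicates, the log2 ratios of replicates 3 and 4 correlated at 0.651, and the other pairs at 0.356 to 0.482. With the scanner's processed signals the values were 0.584 for replicates 3 and 4 and at most 0.407 for the others. By rank (Spearman), replicates 3 and 4 correlated at 0.544 in the main values and the other pairs at only 0.0769 to 0.258. Replicates 3 and 4 had opposite dye orientation, and the pairs with the same orientation, 1 with 3 and 2 with 4, correlated at 0.356 and 0.402. This likeness was noticed before the low antimicrobial peptide ratios of replicate 4, which were weighed in its place after both had been seen.

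The dye term passed the threshold for 0 genes in limma, with 226 at an unadjusted p under 0.05. That is fewer than the share of 0.05 of all tested genes that chance alone would give. The 0 calls therefore do not show that dye effects were absent. Of 12804 tested genes, 11 had probes whose log2 ratios differed by over 1, among them 2 changed genes, and 0 changed genes had probes of opposite sign.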
